A study of Mus musculus with 9 samples.

How the data were processed

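RNA was measured in 9 libraries of laser-captured ileal stem cell niche from AKR mice at 25 weeks, SAMP mice at 5 weeks and SAMP mice at 25 weeks, with 3 biological replicates per group per the labels. Groups were taken from the strain and age in the labels, and replicate numbers follow the order of the samples and pair nothing. The labels also carry a note on cultured crypts, and how it relates to the captured tissue was not stated. Per the submitters' processing notes, Trimmomatic, STAR, HTSeq and DESeq2 were used with the GRCm38 genome, with no versions or order. Which tool made the values, the strandedness and the read length were not given in the sources used here.

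The authors deposited FPKM values, per the file headers, in 1 table of 18220 rows with NCBI gene numbers and RefSeq transcripts. None of the rows was 0 in all 9 libraries. Gene names came from RefSeq's annotation of GRCm38.p6 by gene number for 18155 rows, by transcript accession for 10 and through a GENCODE link for 9, and 46 rows stayed unnamed. FPKM is not a count, so no count test was run. Depth was estimated from the steps between low values of 9740 genes with a single transcript, taking off 50 bp of transcript length. Between 75.2% and 82.1% of low values lay within 0.2 of a whole number of reads, against 40% at random, so whole reads were not recovered for nearly all genes and the depths are estimates.

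Genes with a mean FPKM of at least 1 over the 9 libraries entered the tests, 11775 in all. Values were taken as log2(FPKM + 1), with a pseudocount of 1, so fold changes of low genes are understated. The tests were limma 3.58.1 in R 4.3.3, with all 9 libraries in 1 fit of 3 group means, moderated variances with a trend and Benjamini-Hochberg adjustment within each contrast at 0.05. Errors of log2 fold changes are SE from that fit, and errors of FPKM are SD over 3 libraries. The fit had 6 residual degrees of freedom. A total of 33 gene lists with at least 3 tested members was tested by camera with a preset correlation of 0.01, and again by camera with an estimated correlation and by fry, with adjustment over the lists of a contrast. Mitochondrially encoded genes and immunoglobulin constant genes were not analysed here. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

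The tests, lists, alternatives and the rule for named genes were set before the data were examined. The rule took, per contrast, the 10 genes higher and the 10 lower with the largest log2 fold change among those past the threshold with no overlap between libraries, a fixed set of stem cell, niche, cell type and cell death genes whatever they showed, and 2 to 4 members of each list described. Not every gene the rule takes is given in full. Predicted or unnamed models were counted and not named: 20, 11 and 14 of the called genes of the 3 contrasts. Apoh, Fabp6, Clps, Cela1, Mt1, St3gal6 and Xist with the Y-linked genes are also given, some of them chosen after their values were seen.

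The gene and list tests were checked on simulated data made with the means and spreads of the 11775 genes. For SAMP 25 wk against AKR 25 wk, 41.8% of genes changed by 1 on the log2 scale and 93.6% of those changed by 2 were recovered, with 5.0% of calls false. For SAMP 25 wk against SAMP 5 wk the shares were 36.6% and 93.6%, with 6.1% false, and for SAMP 5 wk against AKR 25 wk 37.4% and 93.2%, with 5.7% false. The simulated genes were independent, so this check says nothing about lists whose genes move together.

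The alternatives were pseudocounts of 0.1 and 5, no filter and a minimum mean of 5, rescaling to TPM, quantile normalization, equal medians, only the groups compared, other variance settings, library weights, a threshold of 0.1 and each replicate left out. A call that ended under at least 4 alternatives is stated beside the gene. Added after the data were seen were rescaling without ribosomal RNA and defensin rows, leaving out both unusual libraries, library weights by a gene-by-gene method and the Paneth list without its defensin members.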

Results

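Gene expression was measured by RNA sequencing in the intestinal stem cell niche, the base of the crypt where stem cells lie between Paneth cells, taken by laser microdissection from the ileum of mice. SAMP/YitFc (SAMP) is a mouse strain that develops a spontaneous Crohn's-like ileitis, and AKR is its control strain. The 9 libraries fell into 3 groups of 3 biological replicates each. AKR mice aged 25 weeks and SAMP mice aged 5 weeks were described as free of inflammation, and SAMP mice aged 25 weeks as having severe ileitis. The values were FPKM for 18220 rows, of which 11775 genes with a mean FPKM of at least 1 were tested. The depth estimated from the steps between low values was 6970000 to 10210000 reads per library, so a gene at an FPKM near 1 rested on few reads. The 10 most abundant rows, which included ribosomal RNA and defensin rows, held 37.8% to 57.3% of the FPKM of a library.

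Single libraries stood apart within their groups. The AKR 25 wk library of replicate 2 was rich in genes of the mature villus enterocyte: Apoa1, an apolipoprotein of enterocytes, was at an FPKM of 1364 in it against 13.3 and 5.92 in the other AKR libraries. Fabp6, the ileal bile acid binding protein, was at 11909 in it against 449 and 224. The first principal component, with 36.4% of the variance, ran from this library to the SAMP 25 wk library of replicate 2. The SAMP 25 wk library of replicate 3 had an FPKM of 176.8 for Xist, the transcript of the inactive X chromosome, and 0.14 for the Y-linked gene Eif2s3y. In the other 8 libraries Xist was between 0.21 and 1.32 and Eif2s3y between 14.53 and 26.97. The sex of the mice was not given in the labels. By these genes the library of replicate 3 came from a female and the other 8 from males. SAMP 25 wk was then the only group of mixed sex, so sex differs in part along with both of its comparisons. Pearson's r of log2(FPKM + 1) across genes between libraries of 1 group was 0.912 to 0.968 in AKR 25 wk, 0.959 to 0.968 in SAMP 5 wk and 0.927 to 0.956 in SAMP 25 wk. Between libraries of different groups r reached 0.946, above the lowest values within AKR 25 wk and SAMP 25 wk. SAMP 25 wk replicate 1 had an r of 0.946 with SAMP 5 wk replicate 1, against 0.927 and 0.956 with SAMP 25 wk replicates 2 and 3.

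The comparison of SAMP 25 wk with AKR 25 wk set diseased mice against control mice of the same age, and strain and ileitis differ together in it. Some genes given below, among them Retnlb, Mptx2 and alpha-defensin genes, also differed between SAMP 5 wk, without inflammation, and AKR 25 wk. In SAMP 25 wk 9 of 11 tuft cell genes and the gasdermin C genes were higher. Of 15 goblet cell genes 7 were higher and 3 lower, and of 10 class II antigen presentation genes 4 were lower, and neither list passed with an estimated correlation (adjusted p = 0.27 and 0.53 with an estimated correlation). Of 23 alpha-defensin genes 6 were higher and 12 lower. The gasdermin C genes Gsdmc2, Gsdmc3 and Gsdmc4 lie side by side on chromosome 15 (63824328 to 63912319, GRCm38) and encode members of a family of pore-forming proteins. Gsdmc2 was at an FPKM of 769.5 ± 384 (SD, n = 3) in SAMP 25 wk and 7.07 ± 0.738 in AKR 25 wk, a log2 fold change of 6.47 ± 0.57 (SE). Pla2g4c, a phospholipase A2 gene on chromosome 7 (13311507 to 13360674), rose by 6.45 ± 0.58 with an adjusted p of 5.4e-05. Retnlb, a goblet cell effector of type 2 immunity, rose from 6.87 ± 1.85 to 520.4 ± 216 (SD, n = 3). Further genes with large increases were Reg4 (4.84), Pnliprp1 (4.67) and Mptx2 (4.85), all on the log2 scale. Zg16, a lectin-like protein of goblet cell mucus, fell by 5.94 ± 0.56 from 1312 ± 1037 to 19.1 ± 13.4. The metallothionein gene Mt2 fell by 4.41 ± 0.46.

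In total 346 of 11775 genes passed an adjusted p of 0.05 in limma's moderated test, 187 higher and 159 lower. The median log2 fold change of all tested genes was -0.15 on the FPKM as deposited, and 54% of the calls were higher. With equal medians the median was -0.01, and 66.7% of 444 calls were higher. With quantile normalization 64.9% of 481 calls were higher. Rescaled to TPM the median was -0.26 and 46.3% of 361 calls were higher, and without SAMP 25 wk replicate 1 the share was 36.6% of 492. The count was 188 without AKR 25 wk replicate 1 and 228 without replicate 2. It was 186 without SAMP 25 wk replicate 2 and 188 without replicate 3.

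Of the 11 tested genes of the tuft cell list, 9 rose and 0 fell. Tuft cells are chemosensory epithelial cells. The median log2 fold change of the list was 1.58, and it passed camera with the preset correlation and with an estimated one (adjusted p = 0.030 with an estimated correlation). With a pseudocount of 5 the median was 0.90, and it ranged up to 1.94 over the alternatives. Rgs13 rose by 2.27 ± 0.34, the interleukin-25 receptor gene Il17rb by 2.10 ± 0.32, the leukotriene synthesis gene Alox5ap by 1.65 ± 0.28 and the transcription factor gene Pou2f3 by 1.58 ± 0.29. Dclk1 rose by 1.33 ± 0.31 (adjusted p = 0.042), a call that ended under 11 of 23 alternatives, with adjusted p up to 0.21. Adjusted over the list alone, 9 tuft genes passed.

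**Figure D1:**
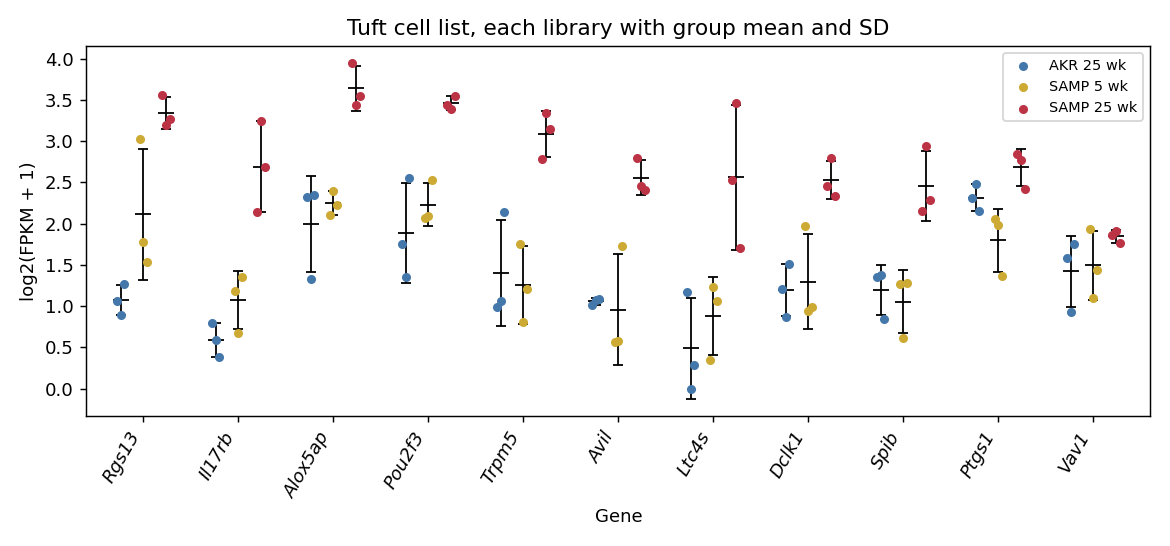
Expression of the tested tuft cell genes as log2(FPKM + 1) on the vertical axis, by gene on the horizontal axis. Each point is 1 library, coloured by group, and the black marks are the group mean and SD (n = 3). Trpm5 had a mean FPKM of 7.62 in SAMP 25 wk against 1.83 in AKR 25 wk and 1.48 in SAMP 5 wk.

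Of the 15 goblet cell genes, 7 rose and 3 fell. The members that rose included the protease gene Klk1 (1.89 ± 0.27), Spink4 (2.48 ± 0.37) and the gel-forming mucin gene Muc2 (1.16 ± 0.27), whose call ended under 11 of 24 alternatives with adjusted p up to 0.15. The members that fell were Zg16, Fcgbp (-3.10 ± 0.49) and Tff3, which encode secreted components of the mucus. Adjusted over the list alone, 14 passed. The list passed the preset camera test with a median of 0.84, and the call was lost with an estimated correlation (adjusted p = 0.27 with an estimated correlation). The type 2, eosinophil and mast cell list held 22 genes with values, of which only 8 passed the filter on low values and were tested. Of these, 3 rose: Retnlb, Kit (1.82 ± 0.29) and the alarmin gene Il33 (1.59 ± 0.32), the last a call that ended under 6 of 23 alternatives. That list's call was also lost with an estimated correlation (adjusted p = 0.065 with an estimated correlation), while it passed fry (adjusted p = 0.0055 with fry).

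**Figure D2:**
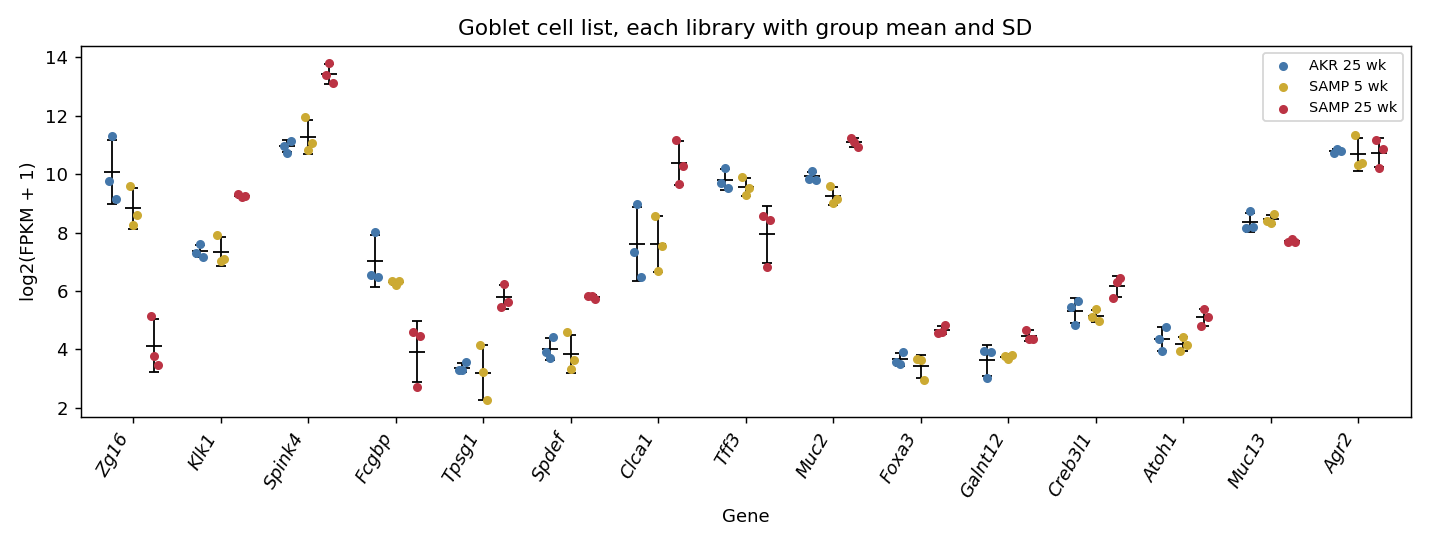
Expression of the tested goblet cell genes as log2(FPKM + 1) on the vertical axis, by gene on the horizontal axis. Points are libraries coloured by group, and black marks are the group mean and SD (n = 3). Muc2 had a mean FPKM of 2175 in SAMP 25 wk and 970.1 in AKR 25 wk, and Zg16 19.1 and 1312.

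Of the 20 tested Paneth cell genes, 6 rose and 5 fell. The antimicrobial ribonuclease gene Ang4 rose by 3.72 ± 0.42 to an FPKM of 12760 ± 3222, and Pnliprp2, a pancreatic lipase related gene, rose by 4.62 ± 0.42. Defa3 fell by 8.19 ± 0.98 and Defa20 by 5.88 ± 0.35, while Defa2 rose by 6.96 ± 0.29 from an FPKM of 56.1 to 7266 and Defa35 by 4.83 ± 0.35. The list's median was 0.88 and its mean -0.31, so the sign of a summary depended on which was taken, and the preset call was lost (adjusted p = 0.71 with an estimated correlation). Lyz1, the Paneth cell lysozyme, had a log2 fold change of -1.73 ± 0.44 and did not pass (adjusted p = 0.064). Defensin genes are near-identical copies that can share reads, and their single values are uncertain. Mmp7 (0.48 ± 0.26) and Wnt3 (0.31 ± 0.30) did not pass.

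Of the 10 class II antigen presentation genes, 4 fell, among them Cd74, the invariant chain, by 1.98 ± 0.34 and H2-DMa by 1.74 ± 0.21. The call for the list was lost with an estimated correlation (adjusted p = 0.53 with an estimated correlation), while it passed fry (adjusted p = 0.037 with fry). Of the 17 macrophage and dendritic cell genes, 3 fell, Fcer1g by 1.85 ± 0.34, Itgam by 1.22 ± 0.22 and Cd68 by 1.31 ± 0.30 (adjusted p = 0.71 for the list with an estimated correlation). The calls of Itgam and Cd68 ended under 4 of 24 and 9 of 23 alternatives. Psmb9 and Psmb8, subunits of the immunoproteasome, fell in the interferon list, 2 of 26 genes (adjusted p = 0.71 for the list with an estimated correlation). Their calls ended under 10 and 13 of 24 alternatives, with adjusted p up to 0.18. The 20 enterocyte genes had a median of -1.60, with 1 higher and 1 lower call, and the 7 bile acid genes a median of -2.04 with 1 lower call, Abcc3. Without the enterocyte-rich AKR library of replicate 2 the medians were -0.72 and -1.24, and both lists still passed the preset test (adjusted p = 0.032 and 0.022). With all 9 libraries, neither passed with an estimated correlation (adjusted p = 0.71 and 0.65 with an estimated correlation). In SAMP 5 wk against AKR 25 wk, both without inflammation, the enterocyte, bile acid and class II lists had medians of -1.52, -1.36 and -0.755. In SAMP 25 wk against SAMP 5 wk the medians of these lists were -0.253, -0.749 and -0.683. The falls against AKR 25 wk were thus in part present in SAMP mice without inflammation. Abcc3 was at an FPKM of 20.5 to 33.2 in the AKR 25 wk libraries and 4.47 to 8.23 in those of SAMP 25 wk. Smooth muscle genes had a median of 0.59 with 0 of 12 genes passing in limma singly, 2 when adjusted over the list alone and 6 at an unadjusted p below 0.05 (adjusted p = 0.57 for the list with an estimated correlation).

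Stem cell markers showed few single changes. Of 21 active crypt-base stem cell genes, Prom1 alone passed (1.08 ± 0.20, adjusted p = 0.013). Lgr5 was at an FPKM of 12.4 ± 2.44 in SAMP 25 wk and 15.85 ± 4.38 in AKR 25 wk (log2 fold change -0.32 ± 0.25). Olfm4 (0.78 ± 0.34), Ascl2 (-0.02 ± 0.30), Smoc2 (-0.25 ± 0.26), Bmi1 (-0.12 ± 0.21) and Hopx (-0.12 ± 0.24) did not pass. Mki67, a proliferation marker, had a value of -0.32 ± 0.25. Dll1, a Notch ligand, and Nrarp, a Notch target, fell by 0.94 ± 0.22 and 0.95 ± 0.21, while Dll4 (-0.55 ± 0.23), Notch1 (0.21 ± 0.26) and Hes1 (-0.53 ± 0.22) did not pass. The call of Dll1 ended under 14 of 23 alternatives and that of Nrarp under 9 of 24, with adjusted p up to 0.18 and 0.16. The necroptosis genes Ripk3 (-0.07 ± 0.32) and Mlkl (0.14 ± 0.37) did not pass, and the inflammatory caspase gene Casp4 fell by 1.54 ± 0.25. Chga (0.83 ± 0.27), Apoa1 (-3.39 ± 1.51) and Reg3g (-3.00 ± 0.77) did not pass. Egf, Rspo3 and Nod2 were below the filter on low values.

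The comparison of SAMP 25 wk with SAMP 5 wk followed the strain from before to after the onset of ileitis, with age as part of the difference. Lipase related genes, Reg4 and gasdermin C genes were higher at 25 weeks, and the Reg3 antimicrobial lectins were lower. Pnliprp2 rose from an FPKM of 56.4 ± 32.8 to 2234 ± 390 (SD, n = 3), a log2 fold change of 5.44 ± 0.42. Reg4 rose by 5.21 ± 0.61, Pla2g4c by 5.43 ± 0.58, Pnliprp1 by 4.67 ± 0.39, Apoh by 4.35 ± 0.38 and the sialyltransferase gene St3gal4 by 3.35 ± 0.29. Gsdmc4, Gsdmc3 and Gsdmc2 rose by 4.05, 3.78 and 3.65, and the call of Gsdmc4 ended under 4 of 24 alternatives with adjusted p up to 0.065. Reg3g fell by 4.79 ± 0.77, from 4649 ± 2066 to 156.9 ± 47.0. Reg3b fell by 5.96 ± 1.21, a call that ended under 7 of 24 alternatives with adjusted p up to 0.15. Zg16 fell by 4.70 ± 0.56, and Serpina10 by 3.96 ± 0.21. The mucosal scavenger receptor gene Dmbt1 had a log2 fold change of -4.08 ± 0.74, and its call ended under 4 of 24 alternatives.

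In this comparison 179 genes passed, 107 higher and 72 lower. The share of higher calls was 59.8%. It was 71.3% of 300 calls with quantile normalization and 70.6% of 248 calls with rescaling that left out ribosomal RNA and defensin rows, an alternative added after the data were seen. Without SAMP 25 wk replicate 1 the count was 528, of which 27.8% were higher. Without SAMP 5 wk replicate 1 it was 130, of which 79.2% were higher, with 103 higher and 27 lower. The count was 82 without SAMP 25 wk replicate 2 and 105 without replicate 3. It was 86 without SAMP 5 wk replicate 2 and 95 without replicate 3.

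The tuft list kept its call, with 5 of 11 genes higher and a median of 1.40 (adjusted p = 0.044 with an estimated correlation). With a pseudocount of 5 the median was 0.73. Adjusted over the list alone, 10 tuft genes passed. Trpm5, the taste transduction channel, rose by 1.83 ± 0.34 and Il17rb by 1.62 ± 0.32, and these calls ended under 6 and 8 of 23 alternatives. Smooth muscle genes moved with them, with a median of 0.85, 0 of 12 passing in limma singly, 4 when adjusted over the list alone and 7 at an unadjusted p below 0.05 (adjusted p = 0.38 for the list with an estimated correlation). Dclk1 had a value of 1.23 ± 0.31 and did not pass (adjusted p = 0.083). Of 15 goblet genes, 6 rose and 2 fell, with Muc2 at 1.82 ± 0.27 and Klk1 at 1.91 ± 0.27 (adjusted p = 0.21 for the list with an estimated correlation and 0.030 with fry). Kit (1.72 ± 0.29) and Retnlb (2.30 ± 0.51) rose in the type 2 list (adjusted p = 0.11 with an estimated correlation and 0.018 with fry). The call of Retnlb ended under 14 of 24 alternatives, with adjusted p up to 0.15. Ang4 rose by 2.87 ± 0.42, and Lyz1 had a value of -1.67 ± 0.44 that did not pass (adjusted p = 0.093). Of 19 antimicrobial and barrier genes 5 fell: Reg3g, Reg3b, Lcn2 (-2.65 ± 0.35), Nos2 (-1.89 ± 0.36) and Cldn2 (-1.34 ± 0.26). The calls of Nos2 and Cldn2 ended under 5 and 7 of 24 alternatives. The list had an adjusted p of 0.52 with an estimated correlation. Of 17 macrophage and dendritic cell genes, Itgam, Cd14 and Fcer1g fell, and the calls of Cd14 and Fcer1g ended under 4 and 5 of 24 alternatives. The interferon list had a median of -0.94, with 15 of 26 genes passing when adjusted over the list alone (adjusted p = 0.52 for the list with an estimated correlation). In limma over all genes 1 of them fell, Irgm2 by 1.45 ± 0.32, a call that ended under 14 of 24 alternatives.

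Among stem cell genes, Aqp4 fell by 1.69 ± 0.22. Lgr5 (-0.73 ± 0.25), Olfm4 (-0.64 ± 0.34), Ascl2 (0.30 ± 0.30), Smoc2 (-0.41 ± 0.26), Bmi1 (-0.10 ± 0.21) and Hopx (-0.30 ± 0.24) did not pass. The 27 cell cycle genes had a median of -0.70 with 0 passing in limma singly, 7 when adjusted over the list alone and 19 at an unadjusted p below 0.05 (adjusted p = 0.52 for the list with an estimated correlation). Cytosolic ribosomal protein genes had a median of -0.71 with 0 of 32 passing in limma and 25 at an unadjusted p below 0.05 (adjusted p = 0.52 with an estimated correlation). Mki67 was at -0.67 ± 0.25, Chga at -0.38 ± 0.27, Ripk3 at -0.43 ± 0.32, Mlkl at 0.05 ± 0.37, Mmp7 at -0.35 ± 0.26 and Wnt3 at 0.57 ± 0.30, and none of these passed. The values of Dll4 (-0.16 ± 0.23), Notch1 (0.16 ± 0.26), Hes1 (-0.48 ± 0.22) and Apoa1 (0.23 ± 1.51) did not pass.

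SAMP 25 wk was also set against both uninflamed groups at once. Of the called genes, 85 were higher and 33 lower than in both groups. Those higher in both included Pla2g4c, Reg4, Pnliprp1, Pnliprp2, Ang4, Retnlb, Muc2 and the genes Gsdmc2, Gsdmc3 and Gsdmc4, and those lower in both included Zg16, Mt2, Fcgbp and Casp4. The SAMP 25 wk libraries entered both contrasts. Independent lists of these lengths would share 1.7 higher and 1.0 lower genes. At an unadjusted p below 0.05, 906 genes differed in the same direction in both contrasts, where independent lists would share 169.8. In 20 simulations of unchanged groups that share libraries the mean was 127.8, where independent lists would share 14.1. Other splits of the 9 libraries, with a group shared by both contrasts in the same way, gave at most 83 genes jointly against 118. This argues against shared libraries without any difference between the groups as the source of the joint count. The other splits mix the groups, which can widen the spread within them. They therefore do not separate the part due to shared libraries from a difference in both contrasts. How much of the excess over independent lists comes from the shared libraries is not known, since these libraries are too few to divide between the contrasts. The joint count was 59 without SAMP 25 wk replicate 2, 73 without replicate 3 and 235 without replicate 1. It was 74 without AKR 25 wk replicate 1, and 65 and 64 without SAMP 5 wk replicates 2 and 3.

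The comparison of SAMP 5 wk with AKR 25 wk set 2 groups without inflammation against each other, and strain and age differ together in it. Alpha-defensin genes, which encode antimicrobial peptides of Paneth cells, were among the genes furthest apart. Of 23 tested defensin genes of this family, 2 were higher and 10 lower in SAMP 5 wk. Defa33 was at an FPKM of 13000 ± 5057 in AKR 25 wk and 46.8 ± 42.7 in SAMP 5 wk (log2 fold change -9.50 ± 1.23). Defa2 was at 56.1 ± 4.49 and 3668 ± 733 (5.99 ± 0.29). These genes lie together on chromosome 8, Defa2 at 21378517 to 21379495 and Defa33 at 21391811 to 21392792, and as near-identical copies they are uncertain as single genes. The same limit holds for Defa21, Defa42, Defa3, Defa20, Defa38 and Defa22, which had log2 fold changes from -8.90 to -5.56, and for Rpl37rt and Ubb-ps, which resemble other genes. Mptx2 (3.78 ± 0.38), Retnlb (3.69 ± 0.51), Card6 (1.95 ± 0.26) and Lcn2 (1.79 ± 0.35) were higher, and Clca3b (-3.36 ± 0.26) and Abcc3 (-1.29 ± 0.25) were lower. The calls of Lcn2 and Abcc3 ended under 13 of 23 and 12 of 24 alternatives, with adjusted p up to 0.20 and 0.22.

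**Figure D3:**
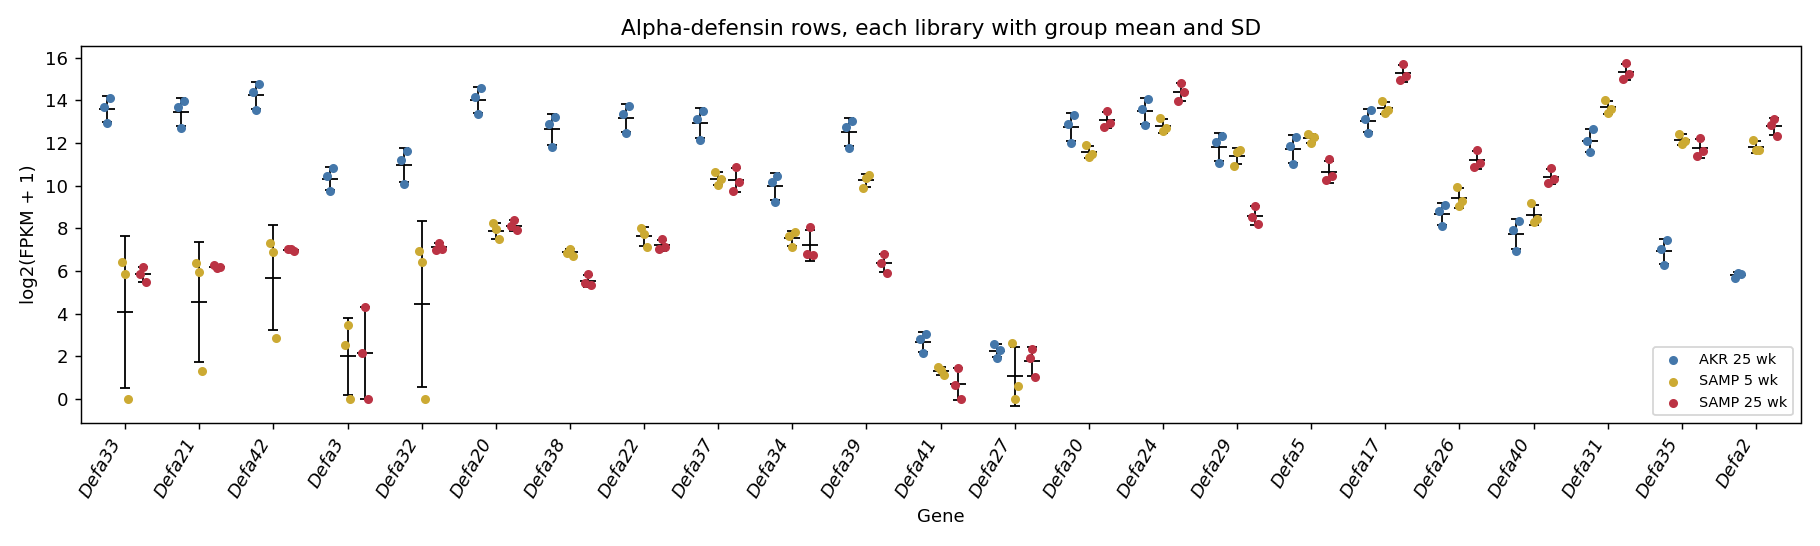
Expression of the tested alpha-defensin genes as log2(FPKM + 1) on the vertical axis, ordered on the horizontal axis by the log2 fold change of SAMP 5 wk against AKR 25 wk. Points are libraries coloured by group, and black marks are the group mean and SD (n = 3). The log2 fold changes ran from -9.50 to 5.99, and single values are uncertain because copies can share reads.

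In this comparison 65 genes passed, 34 higher and 31 lower. The count was 40 without AKR 25 wk replicate 1 and 40 without replicate 3, and 43, 36 and 42 without SAMP 5 wk replicates 1, 2 and 3. Without SAMP 5 wk replicate 1 the balance turned, with 15 higher and 28 lower. Of the 33 lists, 0 passed camera with an estimated correlation and 0 passed fry, with 1 and 3 at an unadjusted p below 0.05. Lgr5 (0.41 ± 0.25), Olfm4 (1.42 ± 0.34), Ascl2 (-0.32 ± 0.30), Lyz1 (-0.06 ± 0.44), Muc2 (-0.66 ± 0.27), Dclk1 (0.10 ± 0.31), Chga (1.21 ± 0.27), Mki67 (0.34 ± 0.25) and Reg3g (1.80 ± 0.77) did not pass. Neither did Smoc2 (0.16 ± 0.26), Bmi1 (-0.02 ± 0.21), Hopx (0.17 ± 0.24), Mmp7 (0.82 ± 0.26), Ang4 (0.85 ± 0.42), Wnt3 (-0.26 ± 0.30), Dll4 (-0.39 ± 0.23), Apoa1 (-3.62 ± 1.51), Notch1 (0.05 ± 0.26), Hes1 (-0.06 ± 0.22), Ripk3 (0.36 ± 0.32) or Mlkl (0.09 ± 0.37). Over the 3 groups, 315 genes passed limma's F test.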

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

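Rescaling without ribosomal RNA and defensin rows, gene-by-gene weights and leaving out 2 libraries were chosen after the data were seen. Among 356 values of named genes, 0 turned direction while past the threshold, and 357 of 8466 comparisons with an alternative lost a call. The 8466 include values that were not called in the main fit and had no call to lose, so the share among called values is larger. The counts of genes stayed within 1.5 times of those reported under both pseudocounts, a minimum mean of 5, rescaling to TPM, equal medians, rescaling without ribosomal RNA and defensin rows, the groups compared alone, no trend and robust variances. Values that moved further are given here for SAMP 25 wk against AKR 25 wk, SAMP 25 wk against SAMP 5 wk, SAMP 5 wk against AKR 25 wk, the F test and the joint count, in this order and leaving out those within 1.5 times. The cause was not tested unless stated. With no filter the second, the F test and the joint count were 99, 203 and 71, with more genes tested. Quantile normalization gave 300 for the second and 191 jointly. A threshold of 0.1 gave 533, 369, an F count of 519 and 213 jointly. Without both unusual libraries the first was 158, the third 40, the F test 158 and the joint count 65, with fewer samples. Leaving out each replicate gave ranges of 186 to 492, 82 to 528, 36 to 70, 176 to 452 and 59 to 235. Library weights gave 2514, 2297, 196, 3042 and 1287. These weights gave SAMP 25 wk replicate 3 a weight of 6.06, and with them the real splits of 6 libraries called 2392, 2209 and 119 genes and the highest of the wrong splits 1350, 2834 and 0, so the larger counts of the first and second comparisons are not taken as a gain in evidence. Gene-by-gene weights gave 718, 707, 159, 831 and 322, with a weight of 2.24 for that library. Of the lists, 17, 16 and 15 passed with the preset correlation, 1, 1 and 0 with an estimated one and 3, 3 and 0 with fry. Those past fry were the tuft, type 2 and class II lists against AKR 25 wk, and the tuft, type 2 and goblet lists against SAMP 5 wk. The stem cell list in SAMP 5 wk against AKR 25 wk changed direction without AKR 25 wk replicate 2 and without both unusual libraries, to a median of -0.078 in each. Its medians ranged from -0.078 to 0.328 when each replicate was left out. No paired analysis was possible because the replicate numbers follow sample order and the labels pair no animals. The depth limits genes near an FPKM of 1. The count tests were not run because the values are not counts.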

Other observations

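The tests of the tuft cells against enteroendocrine cells, of strain alone and age alone, and of the defensin genes were chosen after the result was seen. In SAMP 25 wk the sialyltransferase gene St3gal6 rose by 2.72 ± 0.23 against AKR 25 wk and 2.95 ± 0.23 against SAMP 5 wk. The metallothionein gene Mt1 fell by 2.27 ± 0.26 and 2.11 ± 0.26 (SE, limma). Within SAMP 5 wk, the library of replicate 1 had the highest FPKM of Gsdmc2, 172.7 against 23.3 and 42.6, and of Pla2g4c, 51.0 against at most 8.50. For Gsdmc2, Gsdmc3 and Gsdmc4, every SAMP 5 wk library lay above every AKR 25 wk library. Their log2 fold changes were 2.82 ± 0.57, 2.34 ± 0.53 and 2.38 ± 0.68, and none passed (adjusted p = 0.059, 0.11 and 0.28 in limma). Without their defensin members the 9 remaining Paneth genes had medians of 1.15 and 0.80 against AKR 25 wk and SAMP 5 wk (unadjusted camera p of 0.043 and 0.16 with an estimated correlation).

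The tuft cell genes were higher in SAMP 25 wk than in both other groups. Other scalings of the libraries argue against scaling as the whole cause, since the lowest median over 4 of them and both contrasts was 1.41, and a lowest median of 1.44 without the enterocyte-rich AKR library and the SAMP 25 wk library with Xist argues against either library as the source. A lower share of other epithelial cells would raise enteroendocrine markers too, and the tuft score rose by 1.37 ± 0.22 more than the enteroendocrine score against AKR 25 wk and by 1.74 ± 0.07 more against SAMP 5 wk (SE). This used a single cell type, whose list itself had a mean of -0.42 against SAMP 5 wk. In the same order of contrasts, goblet medians were 0.84 and 1.01 and enterocyte medians -1.60 and -0.25. A shift in the shares of other epithelial cells is therefore not excluded. The tuft score was higher by 1.32 ± 0.15 than in SAMP 5 wk, which argues against a strain difference alone. It was higher by 1.48 ± 0.16 than in AKR 25 wk, which argues against an age difference alone. Both differences are part of the pattern itself, so these values restate it and are no separate test. As a hypothesis, more tuft cells or stronger tuft gene expression may accompany the ileitis, and strain and age effects added together or ageing particular to SAMP stay open without AKR mice at 5 weeks.

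Alpha-defensin genes differed between SAMP 5 wk and AKR 25 wk in both directions. A different amount of Paneth cells would move the other Paneth genes by about as much. The 9 tested had a median log2 fold change of 0.43, with an SD over genes of 1.27 and a range from -0.82 to 3.78. The called defensin genes lay at -2.27 or lower and 5.25 or higher, outside that range in both directions. This argues against the amount of Paneth cells as the whole cause. Those defensin genes were the ones past the threshold, so some distance from no change was given in advance. Reads shared between copies, or copies that the reference lacks, could give such a pattern with a steady sum. The summed FPKM of SAMP 5 wk was 1.08 times that of AKR 25 wk when unnamed rows above 1000 FPKM were included and 0.406 times with the named rows alone, while that of SAMP 25 wk was 1.45 and 0.941 times. At 25 weeks, 6 of 23 tested genes were higher and 12 lower in SAMP than in AKR, while 2 and 2 passed between the SAMP ages. They included Defa2 and Defa35, higher in both strain comparisons, and Defa3, Defa20, Defa21, Defa22, Defa33, Defa38 and Defa42, lower in both. This argues against an age difference alone for these genes. What the unnamed rows encode is not known here. Copy sharing and a true difference with strain, alone or together with age, cannot be told apart.

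The lipase genes Pnliprp1 and Pnliprp2 and the colipase gene Clps rose in SAMP 25 wk, Clps to an FPKM of 4241 from 357.9 in AKR 25 wk and 473.1 in SAMP 5 wk. Of 16 acinar markers 9 were in the table, and the highest of them, Rnase1 at an FPKM of 9.82, reached 0.232% of the Clps level in SAMP 25 wk, with Sycn at 7.47 against 1.47 in AKR 25 wk and 1.60 in SAMP 5 wk, and Cpa1 and Ctrb1 at 0. The elastase gene Cela1, outside that list, was at 17.2 against 8.10 and 4.98, or 0.407% of Clps, and pancreatic tissue would bring acinar enzymes at levels comparable with Clps, which argues against pancreas as the source. The lowest log2 fold change of the lipase and colipase genes was 3.14 ± 0.33 against SAMP 5 wk and 3.62 ± 0.33 against AKR 25 wk, both of Clps, which argues against a strain difference alone and an age difference alone. The genes were grouped by this rise, so these values restate it and are no separate test. A change in crypt cells with the disease, with strain and age together or with ageing particular to SAMP may account for it and stays open.

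Other splits of the libraries were counted for each comparison. Of 100 splits drawn from 280, 1, the real one, gave as many genes in the F test, with 315 genes and at most 138 in another split. That share is under 0.05, which makes chance unlikely there without excluding it. Of 100 drawn from 840, 1, the real one, gave as many genes jointly, with 118 genes and at most 83 in another. For the pairwise comparisons 10 splits are too few for a share under 0.05. The real splits, fitted on 6 libraries, gave 233, 160 and 60 genes and the highest of the others 1, 1 and 0, with 1 of 10 splits as large in each. For the gene lists with the preset correlation, 3, 1 and 3 of 10 splits gave as many lists as the real ones, with 17, 17 and 15 lists in the real splits and 19, 15 and 19 in the highest of the others, so the number of lists passing that test does not by itself set the groups apart.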
